A study of Mus musculus with 6 samples.

How the data were processed

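Gene expression was measured on Affymetrix arrays in plasmacytoid dendritic cells (pDCs), a dendritic cell type known for secreting type I interferon, from the spleens of mice. Per the labels, cells positive for B220 and SiglecH were collected from wild-type (WT) and IRF8-deficient (KO) mice. The series holds 6 samples, 3 per genotype, and the replicate numbers 1 to 3 come from the sample titles. Per the labels' protocols, total RNA was amplified with a NuGen PICO SL kit and labelled with biotin for hybridisation. The labels do not say whether each sample came from its own animal, so p-values of single genes measure the spread between these samples, which may be technical.

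The deposited values are log2 expression levels, 1 per probe set and array, in a table of 34760 probe sets. The log2 scale was read from the values themselves. The authors' software, background correction, summarisation and normalization of the log2 values are not given in the sources used here. The array medians lay between 5.53 and 5.56, so the deposited log2 values had been brought to a common level, and a change of all transcripts in one direction cannot be seen in them. No detection calls were used, so a low level is a low signal and is not called absent. The number of arrays limits the precision.

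Probe sets were named through the platform's annotation table. Of the probe sets, 21640 had 1 gene symbol, 1321 had several and 11799 were not listed there. Probe sets with 1 symbol entered the gene tests, and 21553 of them were matched by Entrez identifier to RefSeq gene names of the mouse assembly GRCm38.p6, which changed 0 symbols. For the 954 genes with several probe sets, the probe set with the highest mean over the 6 arrays stood for the gene. This gave 19937 genes. Coordinates of probe sets are not printed because the sources used here hold no probe positions. After the largest rise was seen, each probe set was checked for a RefSeq transcript shared with its listed gene. The probe sets of 19175 genes shared one. Of the genes that passed the test, 858 did and 16 did not. Of 54 such genes with several probe sets, 7 had a probe set that moved the other way.

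Genotypes were compared per gene with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes on the log2 values without covariates. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. No filter on dim probe sets was applied. Differences are KO minus WT with the standard error (SE) of the fit, and group values are means ± SD. Exact permutation tests of single genes used all 20 relabellings of 3 against 3 arrays, which cannot give a p below 0.10.

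Before the data were examined, 26 gene lists were fixed, covering MYC biology, pDC and conventional dendritic cell identity, metabolism, signalling and the other cell types a B220 and SiglecH gate could hold. Of their 554 entries, 510 were measured. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Camera at the preset correlation does compare them with other genes. Its p-values rest mostly on the spread among genes, so they do not measure the spread between samples. The genes named were fixed by a rule: Irf8, Myc, Mycn, Mycl, Siglech and Ptprc, the 10 largest rises and the 10 largest falls past the threshold whose 3 KO values lay outside the WT range, and up to 4 members of each list past the threshold, or up to 2 as values where none passed. Predicted genes, clone names, small RNAs and olfactory or vomeronasal receptors were left out of the largest changes.

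The gene test was tested on simulated data for this comparison, with 200 changed genes among 19937 in each of 5 runs. It found 7.2% of changes of 0.5 log2 units, 57.2% of changes of 1, 95.2% of changes of 2 and 99.2% of changes of 3, and 4.6% of its calls were false. On simulated lists, camera found 130 of 130 shifted lists and called 4 of 130 unshifted ones. With an estimated correlation it found 129 and called 0. The simulated genes varied independently of each other, while the estimated correlation of the measured lists reached 0.72 for cell cycle and 0.87 for neutrophil genes. These counts therefore do not give camera's errors on lists whose genes move together.

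The alternatives tried were quantile normalization, centring of array medians, a filter for bright genes, the mean of a gene's probe sets, a variance trend with robust estimation, array weights (statmod 1.5.0), the replicate number as a block, leaving out each array and an unequal-variance test per gene. After the data were seen, leaving out both arrays numbered 1 and using RefSeq-matched probe sets alone were added. Figures were drawn with matplotlib 3.10.9.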

Results

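The data were log2 expression levels of 19937 genes in splenic pDCs from 3 WT and 3 IRF8 KO samples. IRF8 is a transcription factor needed for the development of several dendritic cell and monocyte lineages. The series title gives the question: how IRF8 controls the last steps of pDC differentiation and the repression of MYC. Array medians ran from 5.53 to 5.56. The first principal component held 52.8% of the variance and separated the genotypes, and the second, with 23.4%, set both arrays numbered 1 apart from the other 4, with scores of 37.4 for KO replicate 1 and 16.3 for WT replicate 1 against -16.8 to -8.2. Correlations across genes ran from 0.984 to 0.987 within WT, from 0.977 to 0.993 within KO and from 0.961 to 0.969 between genotypes.

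The targeted gene was not lower in the samples labelled KO. Irf8 measured 10.14 ± 0.15 in WT and 10.48 ± 0.32 in KO (SD, n = 3 each), a log2 difference of 0.34 (SE 0.18, limma adjusted p = 0.425, exact permutation p = 0.30). The labels do not say which part of the gene was altered, and a probe set outside that part checks nothing, so this value neither supports nor contradicts the genotype labels. Every direction given here rests on the labels. The gate genes also kept high levels. Siglech, which encodes the SiglecH surface receptor, measured 12.62 in WT and 12.27 in KO (adjusted p = 0.169), and Ptprc, which encodes the protein carrying B220, measured 11.47 and 11.60 (adjusted p = 0.765).

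Myc, a transcription factor that drives growth and proliferation, was 7.39-fold higher in KO. It rose from 6.01 ± 0.17 to 8.89 ± 0.70 (SD, n = 3 each), a log2 difference of 2.88 (SE 0.32, limma adjusted p = 0.00289), and was higher in all 3 KO arrays than in any WT array. The exact permutation p was 0.10, the smallest that 3 against 3 arrays allow. An unequal-variance test per gene did not call Myc (Benjamini-Hochberg adjusted p = 0.342). Its paralog Mycl fell by 0.60 (adjusted p = 0.0426), and this call was lost when any of 5 single arrays was left out, all but KO replicate 1 (highest adjusted p 0.168), with a variance trend (0.0732), with the replicate number as a block (0.0508) and with both arrays numbered 1 left out (0.0517), the last chosen after the data were seen. Mycn measured 4.85 in WT and 5.12 in KO (adjusted p = 0.468). Of the 12 measured genes of the MYC network, Myc was the 1 that rose and Mycl the 1 that fell, both also when adjusted over the list alone. The list's median was -0.06, while its test pointed up (camera adjusted p = 0.758).

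No shift of MYC target genes was detected beside the higher Myc level. Of 55 measured targets, mostly nucleolar, chaperone and replication genes, 0 passed limma's threshold in either direction over all genes and 0 when adjusted over the list alone. The list's median difference was 0.01 and its mean 0.03 (95% interval -0.20 to 0.26, camera adjusted p = 0.401). Its largest differences were 0.78 for Mcm4, a subunit of the replicative helicase (adjusted p = 0.105), and 0.78 for Rcl1, a ribosomal RNA processing factor (adjusted p = 0.0504). Rcl1 passed among bright genes alone (adjusted p = 0.0386), with the mean of probe sets (0.0499), with array weights (0.0345), without KO replicate 1 (0.0491) and with RefSeq-matched probe sets (0.0495), the last chosen after the data were seen. Without KO replicate 1, 2 targets rose and 2 fell: Rcl1 by 0.62 and Dusp2 by 0.55, and Ddx18 by 1.06 and Ndufaf4 by 0.96, the last 3 named after their values were seen. Over all genes, 3203 had an unadjusted p under 0.05. Of 38 further ribosome biogenesis genes, 1 rose and 2 fell over all genes, and 2 rose and 2 fell when adjusted over the list alone (median 0.02, camera adjusted p = 0.625). Dkc1, the pseudouridine synthase dyskerin, rose by 0.84 (adjusted p = 0.00811). Fbl, the methyltransferase fibrillarin, fell by 1.06 (adjusted p = 0.0205) on its brighter probe set, while its second probe set differed by 0.12 (adjusted p = 0.787). Rpf2, an assembly factor of the large ribosomal subunit, fell by 0.55 (adjusted p = 0.0443). The calls of Fbl and Rpf2 were lost without WT replicate 1 or 3 or KO replicate 2 or 3, and that of Rpf2 also without WT replicate 2 (highest adjusted p 0.0857 and 0.171).

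**Figure D1:**
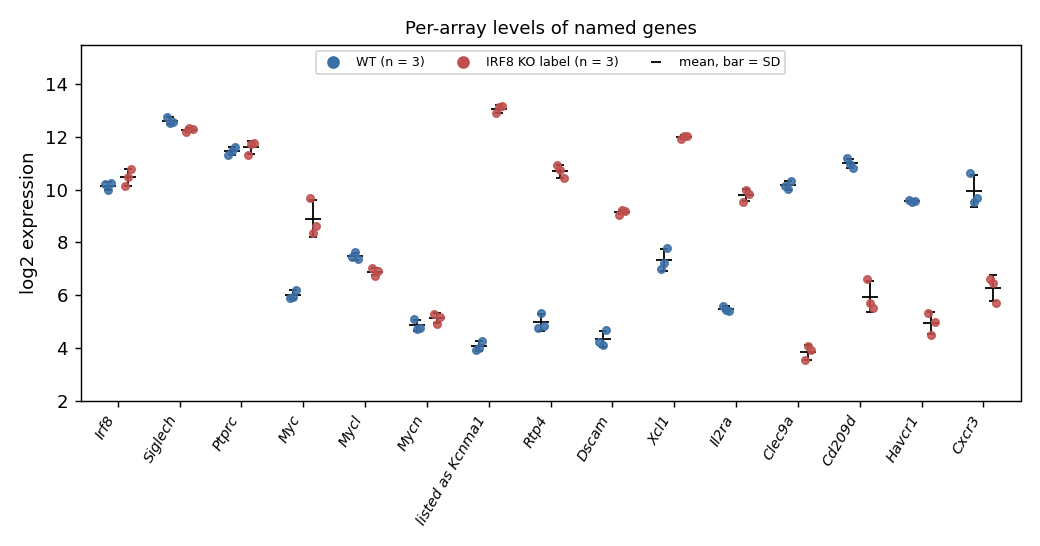
Log2 expression (vertical axis) of 15 named probe sets in each array, with WT in blue and IRF8 KO in red; horizontal marks are means and bars SD of 3 arrays. Myc lay between 8.37 and 9.69 in KO and between 5.90 and 6.20 in WT, while the Irf8 values of the groups overlapped; the probe set listed as Kcnma1 is doubtful in its gene name.

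Across all genes, 459 were higher and 415 lower in KO by limma at an adjusted p of 0.05, together 4.38% of those tested. At least 2-fold changes numbered 264 higher and 226 lower, and at least 8-fold changes 29 higher and 16 lower. In all 874 the 3 KO values lay outside the WT range. The threshold nearly forces this with 3 against 3 arrays, so it adds no evidence for the calls. Over all genes it held for 20.4%, where chance gives 10%. These counts depended on the test and on single arrays. An unequal-variance test per gene gave 2 higher and 2 lower genes, the replicate number as a block 707 and 655, and array weights 716 and 647. Leaving out both arrays numbered 1, chosen after the data were seen, gave 741 and 641. Without KO replicate 1 there were 780 higher and 719 lower genes. Without KO replicate 2 there were 249 and 202, without KO replicate 3 there were 251 and 211, without WT replicate 2 there were 259 and 273, and without WT replicate 3 there were 284 and 219.

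The largest rise belonged to a probe set whose gene name is doubtful. It is listed as Kcnma1, a potassium channel gene, and measured 4.07 ± 0.18 in WT and 13.07 ± 0.15 in KO (SD, n = 3 each), a log2 difference of 9.0 (limma adjusted p = 2.18e-07). None of its listed accessions is a RefSeq transcript of Kcnma1. The other Kcnma1 probe set, which does share such transcripts, measured 4.14 ± 0.14 and 4.05 ± 0.11, a difference of -0.089 (adjusted p = 0.806). The rise is therefore reported for the probe set and not for the gene.

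For 9 named genes past the threshold, 7 of them among the 20 largest changes and the others Clec10a and Cd79a, the lower group's mean lay below the 25th percentile of all levels, 4.56, a limit chosen after the data were seen. No background level was analysed here, so the differences of these 9 are given in log2 units of the deposited values and may understate the change, and ranks are those of the measured values. The other 9 of the 10 largest rises ran from 3.77 to 5.73 log2 units. Rtp4, an interferon-induced transport protein, rose 53.0-fold from 4.97 ± 0.32 to 10.70 ± 0.25 (SD, n = 3 each; limma adjusted p = 1.73e-05). Dscam, a neuronal cell adhesion molecule, rose by 4.82 log2 units, Xcl1, the chemokine ligand of XCR1, rose 25.5-fold, and Il2ra, the alpha chain of the interleukin 2 receptor, 19.9-fold. Ctla4, an inhibitory receptor that binds CD80 and CD86, rose by 4.25 log2 units (adjusted p = 0.00164). Il18r1, a chain of the interleukin 18 receptor, rose by 4.17, and Slc27a2, a fatty acid transporter, by 3.94 log2 units. Sema6d, a semaphorin, rose 16.3-fold and Ms4a6b, a membrane protein of the MS4A family, 13.7-fold.

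The 10 largest falls ran from 3.14 to 6.32 log2 units. Clec9a, a C-type lectin that binds actin of dead cells, fell by 6.32 log2 units from 10.16 ± 0.16 to 3.84 ± 0.28 (SD, n = 3 each; limma adjusted p = 6.67e-06). Cd209d and Cd209a, members of the CD209 lectin family, fell 33.4-fold and 13.2-fold. Havcr1, a phosphatidylserine receptor, fell 24.6-fold, and Cxcr3, a chemokine receptor, 12.9-fold. Grm8, a glutamate receptor, fell by 4.02 and Plxdc2 by 3.33 log2 units, while Gnb4, a G protein subunit, fell 9.05-fold, Klk1b27, a kallikrein, 8.87-fold, and Fyb2 8.83-fold. The CD209 and kallikrein families have similar members that can share a probe set's signal.

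**Figure D2:**
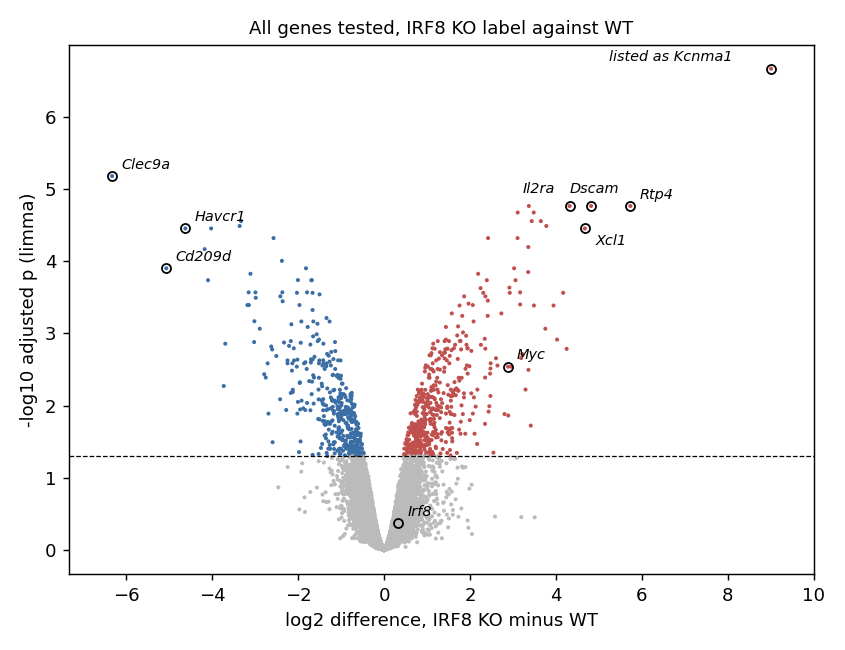
Log2 difference, IRF8 KO minus WT (horizontal axis), against -log10 of the limma adjusted p (vertical axis) for 19937 genes, with genes past 0.05 in red (459 higher) or blue (415 lower) and the dashed line at 0.05. Clec9a lies farthest left at -6.32, Myc at 2.88 lies past the line and Irf8 at 0.34 does not.

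Genes of pDC identity were lower in KO as a list, though not in every member. Of 28 measured, 10 fell and 1 rose over all genes by limma, and 16 fell and 3 rose when adjusted over the list alone. The median was -0.50 (camera adjusted p = 9e-07, and adjusted p = 0.122 with an estimated correlation). Besides Cd209d and Havcr1, Cd300c fell by 2.27 (adjusted p = 0.0115) and Lair1, an inhibitory collagen receptor, by 1.68 (adjusted p = 0.000184). The Cd300c probe set shares no RefSeq transcript with that gene and belongs to a family of similar genes, and its call was lost without WT replicate 2 or WT replicate 3 (highest adjusted p 0.0525). The single rise over all genes was Dntt, a DNA polymerase of early lymphoid cells, named after its values were seen (1.18, adjusted p = 0.00816). Over all genes 17 passed in neither direction, and 7 of the 28 had a positive difference. Among the 17, Tcf4 differed by -0.05 (adjusted p = 0.88) and Bcl11a by 0.19 (0.576), both named after their values were seen.

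Most markers of conventional dendritic cells passed limma's threshold in neither direction, and the others moved both ways. Of 18 genes of the cDC1 type, 2 rose and 2 fell over all genes by limma, and 4 rose and 2 fell when adjusted over the list alone. The median was -0.03 and camera pointed up (adjusted p = 0.985), while fry pointed down (adjusted p = 0.00637). Besides Clec9a, Cadm1, an adhesion molecule, fell by 1.71 (adjusted p = 0.00143). Tlr3, a receptor for double-stranded RNA, rose by 0.87 (adjusted p = 0.0236) and Septin3 by 0.85 (adjusted p = 0.0174). The other 14 passed in neither direction over all genes. Among them Xcr1, named after its values were seen, measured 4.49 in WT and 4.62 in KO (limma adjusted p = 0.792). Of 15 genes of the cDC2 type, 2 rose and 2 fell over all genes, and 2 rose and 4 fell when adjusted over the list alone (median -0.05, camera adjusted p = 0.551). Clec10a, a lectin, fell by 2.62 to a low KO level of 3.96, which can hide part of the fall, and Cd209a fell with it, while Il1r2, a decoy receptor for interleukin 1, rose by 3.41 and Itgam, the integrin CD11b, by 1.89. The calls of Tlr3 and Septin3 were each lost without any of 4 single arrays, WT replicates 2 and 3 and KO replicate 2 among them for both, WT replicate 1 for Tlr3 and KO replicate 3 for Septin3 (highest adjusted p 0.101 and 0.0816), and that of Il1r2 without KO replicate 2 or 3 (0.0832).

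Genes of the cell cycle were higher in KO, by very different amounts in the 3 arrays. All 33 measured genes had a positive difference, but 1 passed limma's threshold over all genes and 1 when adjusted over the list alone: Mcm6, a helicase subunit, rose by 1.44 (adjusted p = 0.0204). Its call was lost without any of WT replicates 1, 2 or 3 or KO replicate 3 (highest adjusted p 0.0873). The list's median was 1.00 (camera adjusted p = 2.67e-11, and adjusted p = 0.451 with an estimated correlation). Its mean difference was 0.93, with a 95% interval of -0.35 to 2.21 that includes no change, and its estimated correlation was 0.72. Its median shift from the WT mean was 1.92 in KO replicate 1, 0.45 in KO replicate 2 and 0.39 in KO replicate 3. Neutrophil granule genes moved with it in KO replicate 1, with shifts of 2.20, 0.18 and 0.06 in the same arrays. Without KO replicate 1 the cell cycle median was 0.46, 7 genes were higher and 0 lower, and camera's adjusted p was 4.9e-10.

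Interferon-stimulated genes rose as a group. Of 23 measured, 14 rose and 0 fell over all genes by limma, and 17 rose and 0 fell when adjusted over the list alone. The median was 1.14, and the call held under both correlations (camera adjusted p = 5.05e-22, and adjusted p = 0.00998 with an estimated correlation). Besides Rtp4, Oas2, a sensor of double-stranded RNA, rose 12.5-fold, and Ifit3 and Ifit1, which restrict viral RNA, rose 9.27-fold and 9.13-fold. Ifit3 has a near-identical copy that can share its signal. The shift lay between 1.05 and 1.27 in the 3 KO arrays.

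Genes of antigen presentation and maturation were also higher. Of 14 measured, 6 rose and 0 fell over all genes by limma, and 10 rose and 1 fell when adjusted over the list alone (median 0.87, camera adjusted p = 1.06e-08, and adjusted p = 0.098 with an estimated correlation). Cd80, a costimulatory ligand, rose 10.2-fold, and H2-Ob, a subunit of the MHC class II chaperone H2-O, 5.33-fold. Cd83, a maturation marker, rose by 1.57 and Ccr7, a lymph node homing receptor, by 1.24. The call of Cd83 was lost without WT replicate 3 or KO replicate 2 (highest adjusted p 0.064) and that of Ccr7 without KO replicate 2 (0.0507). Immediate early and handling stress genes rose in the same order across the KO arrays, with shifts of 0.15, 0.46 and 0.67 in replicates 1 to 3. Antigen presentation genes shifted by 0.44, 0.88 and 1.09 there. The WT arrays did not share this order. In WT replicates 1 to 3 handling stress genes shifted by 0.02, 0.17 and -0.24, and antigen presentation genes by -0.20, 0.02 and 0.10.

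Early progenitor genes and dendritic cell transcription factors were higher. Of 18 progenitor genes, 4 rose and 0 fell over all genes by limma, and 5 rose and 1 fell when adjusted over the list alone (median 0.31, camera adjusted p = 7.75e-05, and adjusted p = 0.098 with an estimated correlation). The median was 0.18 without KO replicate 1 (camera adjusted p = 0.000612), and the shifts in KO replicates 1 to 3 were 0.46, 0.20 and 0.24. Sox4 rose by 1.95, Erg 2.82-fold and Myb by 1.09, all of them transcription factors of immature cells, and Flt3, the receptor of a dendritic cell growth factor, by 0.94. Of 29 transcription factors, 4 rose and 1 fell over all genes, and 13 rose and 3 fell when adjusted over the list alone (median 0.33, camera adjusted p = 3.92e-05, and adjusted p = 0.497 with an estimated correlation). Leaving out single arrays moved the median of the transcription factor list between 0.18, without KO replicate 3, and 0.47, without KO replicate 1. Nfil3 rose by 1.64, Spi1, which encodes PU.1, by 1.13 and Runx1 by 0.80, while Irf5 fell by 0.99. In the KO arrays the shifts of the transcription factor list, 0.20, 0.46 and 0.54 in replicates 1 to 3, lay beside those of the handling stress genes. The latter were 0.15, 0.46 and 0.67. In WT replicates 1 to 3 they did not: the transcription factors shifted by -0.07, -0.11 and 0.21. Handling stress genes shifted by 0.02, 0.17 and -0.24 there. Flt3 lost its call without WT replicate 3 or KO replicate 2 or 3 (highest adjusted p 0.0586), Runx1 without WT replicate 1 or 2 or KO replicate 2 or 3 (0.113), and Irf5 without WT replicate 3 or KO replicate 3 (0.0667).

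Toll-like receptor signalling genes were lower. Of 19 measured, 0 rose and 3 fell over all genes by limma, and 1 rose and 7 fell when adjusted over the list alone (median -0.28, camera adjusted p = 0.013, and adjusted p = 0.135 with an estimated correlation). The call was lost among bright genes alone (median -0.31, adjusted p = 0.0516), without KO replicate 1 (-0.32, 0.126) and with both arrays numbered 1 left out (-0.22, 0.237), the last chosen after the data were seen. Besides Irf5, Tlr12, a receptor for profilin, fell by 0.96 (adjusted p = 0.00497) and Tlr7, the receptor for single-stranded RNA, by 0.60 (adjusted p = 0.0484). Tlr7 lost its call without any single array but KO replicate 1 (highest adjusted p 0.165).

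BCL2 family genes and chemokine receptors changed in part. Of 13 BCL2 family genes, 3 rose and 0 fell over all genes by limma, and 5 rose and 0 fell when adjusted over the list alone (median 0.08, camera adjusted p = 0.00155, and adjusted p = 0.098 with an estimated correlation). Leaving out single arrays moved this median between 0.04, without WT replicate 3, and 0.14, without WT replicate 1. The survival factor Bcl2 rose by 1.59 (adjusted p = 0.00735), and the death-promoting Bid and Pmaip1 rose by 0.85 and 0.57. Bid lost its call without any WT replicate or KO replicate 3 (highest adjusted p 0.105), and Pmaip1 without any single array but KO replicate 1 (0.191). Of 14 chemokine receptor and homing genes, 2 rose and 3 fell over all genes, and 3 rose and 3 fell when adjusted over the list alone (median -0.13, camera adjusted p = 0.85). That median was 0.06 without WT replicate 1. Besides Cxcr3, Cmklr1, the chemerin receptor, fell by 1.02 and Ccr9, a gut homing receptor, by 0.97. Cmklr1 lost its call without WT replicate 1 or 3 or KO replicate 2 or 3 (0.106), and Ccr9 without WT replicate 2 or 3 or KO replicate 2 or 3 (0.0817).

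Of the metabolic lists, 1 passed. Of 24 nucleotide and one-carbon synthesis genes, 1 rose and 0 fell over all genes by limma, and 2 rose and 0 fell when adjusted over the list alone (median 0.30, camera adjusted p = 0.000813, and adjusted p = 0.098 with an estimated correlation). The median was 0.19 without KO replicate 1 (camera adjusted p = 0.00403). The purine enzyme Paics rose by 0.66 (adjusted p = 0.0386) and lost its call without any single array but KO replicate 1 (highest adjusted p 0.16). Of 17 glycolysis genes, 0 rose and 2 fell over all genes, and 2 rose and 2 fell when adjusted over the list alone (median 0.19, camera adjusted p = 0.125). Ldhb, a lactate dehydrogenase subunit, fell by 2.13 and Aldoc, an aldolase, by 0.66. Aldoc lost its call without any WT replicate or KO replicate 2 (highest adjusted p 0.107), with differences from -0.58 to -0.69. The glycolysis list passed without KO replicate 1 (median 0.36, camera adjusted p = 0.0107), with array weights (0.32, 0.0332) and with both arrays numbered 1 left out (0.35, 0.00885), the last chosen after the data were seen. Without KO replicate 3 its median was 0.04 (camera adjusted p = 0.35). Of 18 oxidative phosphorylation genes, 0 passed over all genes and 0 over the list alone (median 0.02, camera adjusted p = 0.217), and the largest differences were 0.62 for Atp5a1 (adjusted p = 0.154) and 0.47 for Atp5b (adjusted p = 0.117). Atp5a1 passed with array weights (adjusted p = 0.0314), without KO replicate 1 (0.85, adjusted p = 0.0074) and with both arrays numbered 1 left out (adjusted p = 0.015). Of 23 genes of protein folding in the endoplasmic reticulum, 0 rose and 3 fell, over all genes and over the list alone (median -0.12, camera adjusted p = 0.176). Edem2 fell by 1.00, Creld2 by 0.74 and Herpud1 by 0.64. Creld2 and Herpud1 lost their calls without any single array but KO replicate 1 (highest adjusted p 0.151 and 0.105), with differences from -0.61 to -0.86 and from -0.56 to -0.69. This list passed without KO replicate 3 (median -0.23, camera adjusted p = 0.00495) and after quantile normalization (-0.17, 0.0345). Without KO replicate 1 its median was -0.035 (camera adjusted p = 0.821). The list's shifts in KO replicates 1 to 3 were -0.44, -0.08 and 0.07, so its lower median rested mostly on KO replicate 1.

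Marker lists of other cell types did not move alike. Of 16 B cell genes, 6 rose and 0 fell over all genes by limma, and 8 rose and 0 fell when adjusted over the list alone (median 0.25, camera adjusted p = 2.52e-05, and adjusted p = 0.098 with an estimated correlation). Bank1 rose by 2.47, Blk by 2.42, Cd79a by 1.65 from a low WT level of 4.07 and Cd22 by 1.51, genes of B cell receptor signalling, and Cd22 lost its call without WT replicate 2 or 3 or KO replicate 3 (highest adjusted p 0.0922). Of 9 plasma cell genes, 2 rose and 1 fell, over all genes and over the list alone (median -0.06, test pointing up, camera adjusted p = 0.316). That median was 0.13 without KO replicate 1. Prdm1, which encodes BLIMP1, rose 11.2-fold and Sdc1, which encodes CD138, 5.57-fold, while Txndc5 fell by 1.22. Txndc5 lost its call without WT replicate 1 or 3 or KO replicate 3 (highest adjusted p 0.0997), with differences from -1.14 to -1.29. Of 9 T cell genes, 1 rose and 0 fell, over all genes and over the list alone (median -0.03, test pointing up, camera adjusted p = 0.783): Cd5 rose by 1.09 and lost its call without WT replicate 2 or KO replicate 2 or 3 (highest adjusted p 0.0779), with differences from 1.04 to 1.12. Of 10 NK cell genes, 0 rose and 1 fell over all genes, and 2 rose and 2 fell when adjusted over the list alone (median 0.22, camera adjusted p = 0.523), and Klrk1, which encodes NKG2D, fell by 1.26 (adjusted p = 0.00656). The median of the NK list was -0.02 without KO replicate 1.

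Marker lists of myeloid and erythroid cells did not move alike either. Of 17 monocyte and macrophage genes, 0 rose and 2 fell over all genes by limma, and 0 rose and 4 fell when adjusted over the list alone (median -0.33, camera adjusted p = 0.013, and adjusted p = 0.497 with an estimated correlation). WT replicate 1 stood apart. The list's shifts were -0.33, 0.20 and 0.07 in WT replicates 1 to 3 and -0.20, -0.53 and -0.40 in the KO replicates. KO replicates 2 and 3 lay below every WT array, while KO replicate 1 lay above WT replicate 1. The lysosomal protein gene Cd68 fell by 1.55 and the complement gene C1qb by 1.47. The list's call was lost among bright genes alone (median -0.52, adjusted p = 0.189), without WT replicate 2 (-0.20, 0.0524) or WT replicate 3 (-0.30, 0.0768) and by fry (0.0857). It was kept without WT replicate 1 (-0.50, 1e-05) and with both arrays numbered 1 left out, where 1 gene was higher and 7 lower (-0.56, 2.05e-05), the latter chosen after the data were seen. C1qb measured 5.66, 6.99 and 6.57 in WT replicates 1 to 3, and its call was lost without WT replicate 2 or 3 or KO replicate 2 or 3 (highest adjusted p 0.137). Of 17 neutrophil genes, 0 passed over all genes and 0 over the list alone, although the median was 0.89 (camera adjusted p = 0.000459, and adjusted p = 0.633 with an estimated correlation). S100a8 measured 12.70, 8.99 and 7.48 in KO replicates 1 to 3 and 9.34, 4.87 and 4.44 in the WT replicates (adjusted p = 0.351), and S100a9 differed by 3.19 (adjusted p = 0.349). With the replicate number as a block both passed (adjusted p = 0.000314 and 0.00126), and S100a8 also passed with both arrays numbered 1 left out, an alternative chosen after the data were seen (0.00589). The list's shifts in WT replicates 1 to 3 were 0.23, -0.07 and -0.17. Without KO replicate 1 the list's median was 0.02 and its call ended (adjusted p = 0.148), while with both arrays numbered 1 left out the median was 0.18, 2 genes were higher and the call held (adjusted p = 0.00226). Of 8 erythroid genes, 0 passed over all genes and 0 over the list alone (median 0.06, camera adjusted p = 0.245), and the largest differences were 1.15 for Car1 (adjusted p = 0.122) and 0.21 for Klf1 (adjusted p = 0.589). Of 13 immediate early and handling stress genes, 1 rose and 0 fell, over all genes and over the list alone (median 0.30, camera adjusted p = 0.000443, and adjusted p = 0.211 with an estimated correlation), and Ier3 rose by 2.48 (adjusted p = 0.0026). Without KO replicate 1, 3 genes of this list were higher and 0 lower (median 0.55, camera adjusted p = 4.65e-05).

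**Figure D3:**
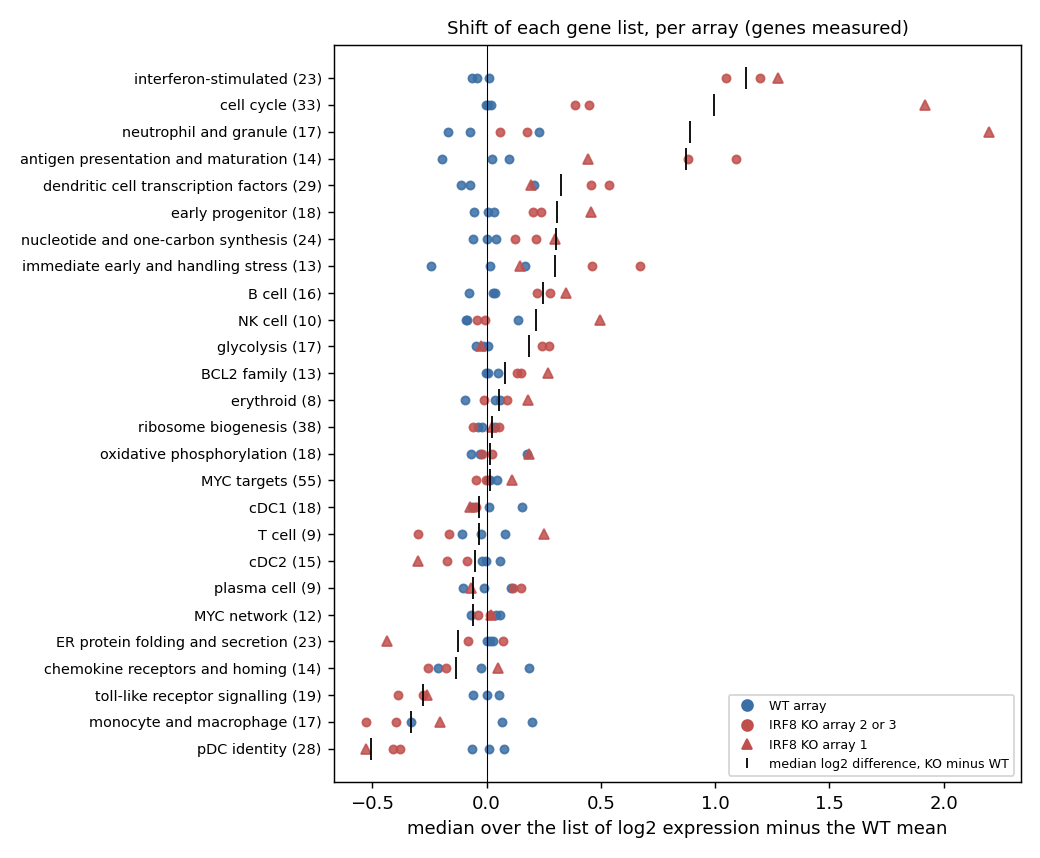
Median over each gene list of log2 expression minus the WT mean (horizontal axis), 1 row per list with the number of genes measured; dots are arrays, triangles KO replicate 1 and vertical ticks the median difference, KO minus WT. Interferon-stimulated genes lay above 1 in all 3 KO arrays, and KO replicate 1 stood at 1.92 for cell cycle and 2.20 for neutrophil genes, apart from the other KO arrays.

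Of the 26 lists, 13 passed camera's threshold with the preset correlation, 10 up and 3 down. With an estimated correlation 1 list passed, the interferon-stimulated genes. Nucleotide and one-carbon synthesis (-0.0018), early progenitor (-0.014), BCL2 family (-0.0028) and toll-like receptor signalling (-0.014) lost calls with estimates below the preset 0.01. A higher correlation between genes therefore does not account for these lost calls. Fry passed 10 lists, 8 of them shared with camera.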

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

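The probe sets outside the gene tests were set aside before the data were examined, and so were the counts over other splits of the samples. All tests of the 3 patterns below were chosen after the result was seen.

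Probe sets that name no single gene also held signals that differed between the genotypes by limma. Of 11799 without a listed gene, 2 were higher and 4 lower in KO, with differences of up to 3.22 and down to -5.97. Of 1321 listed with several genes, 11 were higher and 7 lower, with differences of up to 3.99 and down to -1.86.

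Neutrophil granule and cell cycle genes stood highest in KO replicate 1. Neutrophil-lineage cells in that sample are a candidate source that stays open: 17 of 17 measured neutrophil genes were highest there and S100a8 reached 12.70, but this count restates the pattern and does not test its source. The lower of the cell cycle shifts in KO replicates 2 and 3 was 0.39. WT arrays, measured from their own mean, ran from -0.00 to 0.02. This does not exclude the same cells as the whole cause of the rise, because KO replicates 2 and 3 may hold them too. S100a8 measured 8.99 and 7.48 in these 2 arrays, against 9.34, 4.87 and 4.44 in WT replicates 1 to 3. The neutrophil list shifted by 0.18 and 0.06 in KO replicates 2 and 3 and by 0.23 in WT replicate 1. The cell cycle shift of WT replicate 1 was -0.004, so it had as much neutrophil signal without the cell cycle rise. That comparison rests on 1 WT array and does not decide the question. Whether those cells also brought the excess of 1.47 log2 units in cell cycle genes over the other KO arrays cannot be told apart from a difference of the pDCs themselves, because both lie in 1 array. The B220 and SiglecH gate should remove neutrophils, and more of them in the spleen of KO mice stays open and was not tested.

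Blk, Bank1, Cd79a and Cd22 rose together by a mean of 2.01 log2 units (95% interval 1.72 to 2.30), where Cd79a had a low WT level of 4.07, and B cells carry B220, though the SiglecH part of the gate should remove them. The first test used Ms4a1, Cd79b and Ighm, whose mean difference was -0.026 (95% interval -0.33 to 0.28), but it decides nothing because Ms4a1 had a low WT level of 3.56 and Cd79b had a high WT level of 8.26. A second test, added after that result was seen, used the 7 other B cell genes with WT levels in the range of the 4, of which Fcer2a and Chst3 passed as higher; their mean difference was 0.24 (95% interval 0.0049 to 0.48), but it decides nothing either, because the 4 genes are the list's largest rises and the rest lie lower by selection. Cells that came with KO replicate 1 alone are argued against, since 4 of the 4 genes passed without that array. B cells in all KO samples may be the source, as may expression of these genes by KO pDCs, and both stay open.

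Myc rose while no shift of the MYC target list was detected. Probe sets too dim to show a change stay open: 92.7% of the list (51 of 55 genes) lay above the median level of all genes, but levels of different probe sets are not comparable and no background level was analysed. An opposite shift in KO replicate 1 is argued against, since the list's mean difference without it was -0.053. A normalization across arrays that removed a rise of all transcripts could produce this pattern and stays open, since the array medians span 0.034 log2 units and no external control RNA was in the values used. A biological difference between Myc transcript and MYC activity also stays open and was not tested.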

How the results depend on the processing

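The alternatives were fixed before the data were examined, except leaving out both arrays numbered 1 and using RefSeq-matched probe sets alone. Under the alternatives fitted with limma, Myc stayed past the threshold, between 2.43 and 3.15, and Irf8 short of it. Welch's test per gene did not call Myc (adjusted p = 0.342) or Irf8 (0.66). Of the 874 genes, 848 were also called after quantile normalization, 855 with array medians centred, 857 with the mean of probe sets, 773 with a variance trend, 755 among bright genes alone and 858 with RefSeq-matched probe sets, which set the gene Kcnma1 at -0.089, no longer past the threshold and with the sign turned, because another probe set stands for it. Array weights gave 716 higher and 647 lower genes, and leaving out both arrays numbered 1 gave 741 and 641. The cause was not tested. Leaving out single arrays gave 249 to 780 higher and 202 to 719 lower genes. Of 74 named genes past the threshold, 48 passed without any 1 array; the other 26 lost a call 96 times, each time with the same sign and at 80.1% to 115.1% of the main difference. With a variance trend 7 named genes missed the threshold, Mycl, Rpf2, Paics, Creld2, Herpud1, Tlr7 and Pmaip1, and with both arrays numbered 1 left out 9 did. Pmaip1 missed it after quantile normalization, Tlr7 with medians centred and Fbl with the mean of probe sets. Welch's test gave 2 higher genes, Atp8b4 and the probe set listed as Kcnma1, and 2 lower, Enpp5 and Lair1 (unadjusted 912 and 1171); Atp8b4 and Enpp5 were named after their values were seen.

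With the replicate number as a block, 707 genes were higher and 655 lower. S100a8 (adjusted p = 0.000314) and S100a9 (0.00126) passed under the block and Mycl (0.0508) did not. The labels do not say whether the numbers pair the samples, and the data leave it undetermined. Each gene's deviations from its genotype mean were correlated between arrays of different genotype. Same-numbered arrays gave 0.38, 0.097 and 0.25, of which 2 of 3 exceeded 0.1. For 5 of 6 arrays the best match in the other genotype had their own number.

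With an estimated correlation the pDC identity list at -0.50 (adjusted p = 0.122) and the cell cycle list at 1.00 (0.451) missed the threshold. By fry, cell cycle at 1.00 (0.194), dendritic cell transcription factors (0.144), monocyte and macrophage (0.0857), neutrophil (0.494) and handling stress genes (0.0635) missed it, while cDC2 at -0.051 (0.0113) and cDC1 at -0.033 (0.00637, downward where camera pointed up) passed. Fry and camera ask different questions. The alternative for linear values was not run because the values are on a log2 scale. Signal over background was not analysed here and limits what dim genes show.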

Other observations

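The tests of gene families were chosen after the data were seen, while the counts over other splits were planned.

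Families of genes that share the first letters of their symbols were compared with all genes. Of 660 tests on 330 families, 7 passed by Fisher's exact test with Benjamini-Hochberg adjustment. That test counts genes as units, so its p-values do not measure the spread between samples. Interleukin and interleukin receptor genes rose in 10 of 76 cases (adjusted p = 0.002), among them Il12a, Il1b and Il18rap. Interferon-inducible Ifi genes rose in 5 of 15 (adjusted p = 0.00207), Oas genes in 4 of 9 (adjusted p = 0.00351) and Parp genes in 4 of 11 (adjusted p = 0.00759). Gimap genes, small GTPases of lymphocytes, fell in 4 of 8 (adjusted p = 0.002): Gimap1, Gimap5, Gimap6 and Gimap9. Genes whose symbol starts with Cd, a naming scheme and not a function, rose in 14 of 94 and fell in 12 (adjusted p = 2.07e-05 and 0.000191). These genes were named after their values were seen, and members of the Ifi, Oas and Gimap families can share probe signal.

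Of the 100 measured genes nearest to Irf8 on its chromosome, 2 passed the test against 4.38% of all genes (Fisher's exact p = 0.329).

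The 6 arrays allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 874 genes and the highest other split 0. At least 2-fold changes numbered 490 and 0. The lists past camera's threshold numbered 13 and 9, and with an estimated correlation 1 and 0. For each of these 4 results, 1 of the 10 splits, the real one, gave as many. Each of the other splits still sets 2 arrays of a genotype against 1 on a side, so part of the genotype difference remains in them. The genotype difference also widens the spread within their groups, which lowers the number of genes they call. Their gene counts of 0 therefore do not exclude chance.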
